A study of Homo sapiens with 4 samples.

How the data were processed

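Gene expression was measured in T-47D cells, an established line of hormone receptor-positive luminal breast cancer, on Affymetrix exon arrays. One group of 2 arrays came from cells transfected with a mimic of p-27-5p, an artificial microRNA. The other group of 2 arrays came from cells transfected with a pre-miR negative control. The cells were transfected with TurboFect reagent, and the mimic was used at 200 nM, per the labels' protocols. The labels give no dose of the control separately, no time between transfection and RNA extraction, and no sequence of the mimic. Target sites of the mimic were not analysed here. Nothing in the labels says whether the 2 arrays of a group came from separate cultures, so the p-values measure only the spread between these arrays, which may be technical.

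The deposited table holds log2 values, 1 per exon-level probeset and array, for 232479 probesets. A probeset is a small set of probes that reads about 1 exon or part of an exon. The submitters' processing notes name Partek, the RMA method and the genome build hg18, with no version or order of steps. RMA usually corrects background, quantile-normalizes and summarises probes on the log2 scale, but the deposited log2 values do not share 1 distribution. Their interquartile range was 4.18 and 4.32 on the mimic arrays and 4.25 and 4.52 on the control arrays. No probeset-level detection calls were used. Signal over background was judged from 16 genes of liver and neurons, whose median level in the control arrays was 4.79 and whose highest was 5.68 on the log2 scale. Genes near those levels have little signal over background, and fold changes against such a level understate the change. The small number of arrays limits the precision of every value.

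Gene symbols came from GEO's platform annotation and were updated through a table of current RefSeq symbols. In the table, 216780 probesets carried 1 symbol, 2335 carried several and 13364 were unnamed. Of those with 1 symbol, 190058 had a current symbol, 25769 were updated through a synonym and 953 were kept as listed. No gene was named from a probeset with several symbols. No coordinates are given, since no genome of the build used was analysed here.

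Before the data were examined, the tests, the gene lists, the rule for named genes and most alternatives were fixed. A gene's value was the mean log2 value of its probesets that name exactly 1 gene and whose mean over the 4 arrays was at or above the 25th percentile of the table, which was 4.08. This left 174802 probesets and 15719 genes. The mimic and control groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), with Benjamini-Hochberg adjustment and a threshold of 0.05. The fit had 2 residual degrees of freedom, and 5.29 with the prior. SD is the spread of the 2 arrays of a group, and SE is that of limma's moderated fit. Fold changes are mimic minus control on the log2 scale. The same test was run on single probesets. Tables were read with the data.table package, version 1.17.8, and plots were drawn with matplotlib 3.10.9 in Python 3.11.15.

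A total of 32 gene lists, of pathways, cell types and controls, were tested with limma's camera at its preset correlation of 0.01, with adjustment over the lists. Camera with an estimated correlation and fry were alternatives. With an estimated correlation the test rests on the 2 residual degrees of freedom, which by itself raises p. For immediate-early genes, with an estimated correlation of -0.032, camera's unadjusted p went from 0.0107 to 0.102. For interferon-stimulated genes it went from 6.4e-71 to 0.0183. A missed threshold there therefore does not by itself show that a list owed its call to correlation between genes. For DNA replication and for G2/M and mitosis the estimated correlation was 0.373 and 0.556, which raises p as well. Their unadjusted p was 0.167 and 0.296 there, and their calls at the preset may rest on correlation between genes. Fry asks whether a list's genes move one way on balance and does not compare them with other genes. Another 7 lists were put together after the data were seen and are used only in the closing section. Unequal change across the probesets of a gene was tested with limma's diffSplice F test in 14389 genes. The genes named are the 12 largest increases and the 12 largest decreases past the threshold, CDK4, the 4 members with the smallest p of each list past the threshold and of the cyclin D axis, up to 2 of any other list, and the 3 genes with the smallest p for unequal change. Other genes named are said to have been chosen after their values were seen, or are members of a fixed list given as examples.

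The alternatives were a replicate block, quantile normalization, equal array medians, no filter or a stricter filter on dim probesets, leaving out each array in turn, the median or the brightest probeset of a gene, an intensity trend, robust hyperparameters, a fold threshold and a looser threshold of 0.1. Cyclic loess normalization, a test of single probesets' deviations, and an estimated correlation together with the brightest probeset or with quantile normalization were added after the data were seen. With 1 array left out, the lone array of a group is assumed to vary like the other group. Such a fit has fewer residual degrees of freedom, so a gene can lose its call there at a nearly unchanged fold change.

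The submitters describe the mimic and control samples as paired, without naming a shared day or batch, and the replicate numbers 1 and 2 are shared between the groups. As a check, the differences between replicates 1 and 2 were correlated between the groups across genes. The correlation was r = 0.435 over 15719 genes, and r = 0.370 after quantile normalization. Genes are not independent replicates, and 2 pairs cannot settle the matter. The fit without the block is the main one, and the blocked value is given where it changes a call or moves a count by more than 1.5 times.

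The tests were run on simulated data with known changes first. In the gene test, simulated in 15719 genes with 50 changed genes per size, 2% of changes of 0.5 on the log2 scale were recovered, 30% of changes of 1, 98% of changes of 2 and 98% of changes of 4. Of 120 genes called there, 6 had no simulated change. The list test recovered 3 of 3 shifted lists and called 0 of 29 others. These simulated lists held random genes with independent noise, so they do not measure false calls in lists of correlated genes. In the data the estimated correlation was 0.373 for DNA replication and 0.556 for G2/M and mitosis. The F test for unequal change recovered 112 of 200 simulated genes, but 253 of its 365 calls were false when probesets had unequal variance. A test of single probesets' deviations, tried in its place after this was seen, recovered 0 of the 200. Some genes are not reported here.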

Results

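The data are 4 exon arrays of T-47D cells, 2 from cells transfected with the p-27-5p mimic at 200 nM and 2 from cells transfected with a pre-miR negative control. Each array gave a log2 value per exon-level probeset. Across all probesets the array values correlated with r = 0.985 between the mimic arrays, r = 0.984 between the control arrays and r from 0.966 to 0.973 between a mimic and a control array. The comparison asks which transcripts differ between cells given the artificial microRNA and cells given the control, with CDK4, a kinase that drives entry into S phase, as the transcript of interest from what is known of the study. All values below are log2 levels with n = 2 arrays per group, and tests are limma's with Benjamini-Hochberg adjustment.

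Interferon-stimulated genes made up the largest increases. Of 42 measured members of this list, 41 rose, and all 42 passed when adjusted over the list alone. The list median was 3.77, and 11 of the 12 largest increases past the threshold were members of it. IFIT3, which binds viral RNA together with IFIT1, rose by 7.66 (SE 0.151), from 4.32 ± 0.096 (SD, n = 2) in control arrays to 11.97 ± 0.197 (SD, n = 2) in mimic arrays, a 202-fold change with a limma adjusted p of 0.000122. OAS2, which makes the signal that activates RNase L when it meets double-stranded RNA, rose by 7.12 (SE 0.132). IFIT2, IFI27, TRIM22, OAS1, IFIT1, IFI44L, IFI44, DDX60 and OASL rose by 5.51 to 6.79. The control levels of the 12 largest increases lay between 3.38 and 6.89. All but that of IFIT1 lay within the range, up to 5.68, of the liver and neuron genes that serve as background. Their fold changes, that of IFIT3 among them, may therefore understate the change. The RNA sensors RIGI and IFIH1 rose by 4.23 and 3.78, the antiviral GTPase MX1 by 4.79, and IFNL1, a secreted type III interferon, by 3.28. XAF1, with 1.23 (adjusted p = 0.098), was the 1 measured member that did not pass. It did with the replicate block (adjusted p = 0.0394), without mimic replicate 2 (0.0429) and without control replicate 1 (0.00224) or 2 (0.0299). Camera gave the list an adjusted p of 2.0e-69 at its preset correlation, against an adjusted p of 0.579 with an estimated correlation. Fry gave an adjusted p of 0.00497.

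**Figure D1:**
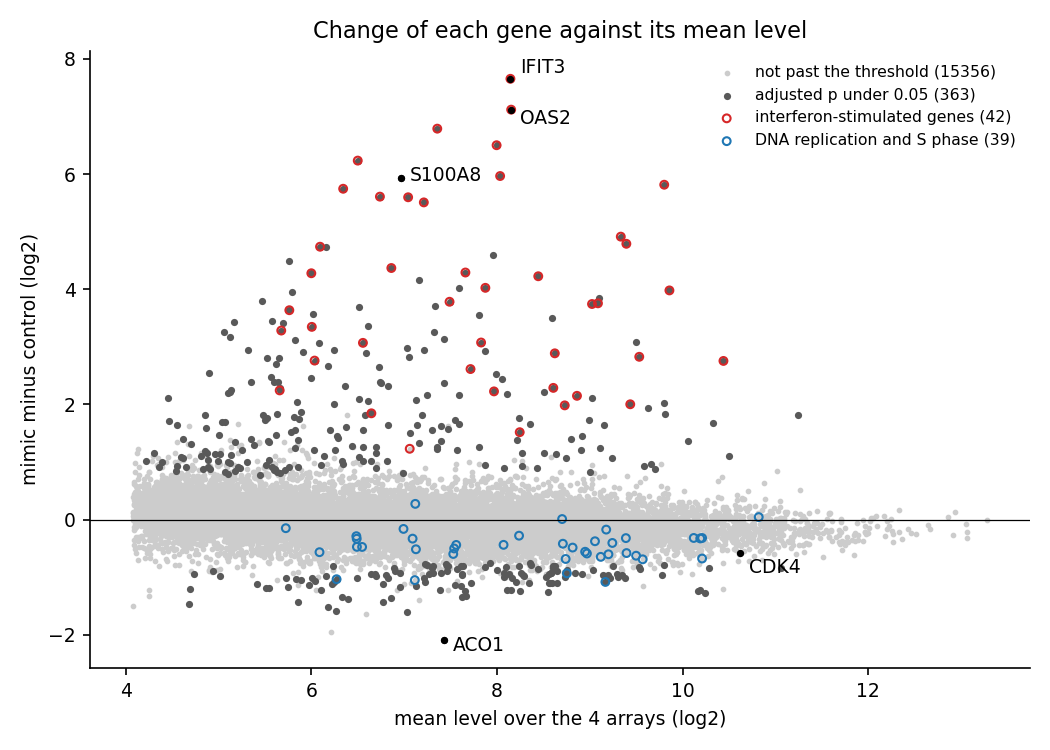
Change of each of 15719 genes (mimic minus control, log2, vertical axis) against its mean level over the 4 arrays (log2, horizontal axis), with 1 point per gene. Dark points are the 363 genes with an adjusted p under 0.05, red circles the 42 interferon-stimulated genes, which reach 7.66 for IFIT3, and blue circles the 39 replication genes, whose median is -0.47.

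Inflammatory genes were also higher. Of 27 measured NF-kB and inflammatory genes, 13 rose, 14 did not pass and none fell, with 17 higher when adjusted over the list alone. CCL5, a chemokine that attracts T cells, rose by 4.16 (SE 0.210). BIRC3, an inhibitor of apoptosis, rose by 2.65 (SE 0.159), TNFAIP3, a brake on NF-kB signalling, by 2.80 (SE 0.143) and the adhesion molecule ICAM1 by 2.46 (SE 0.127). CXCL8 had 0.47 (adjusted p = 0.303, and 0.0407 without control replicate 1). The list median was 1.14, with a camera adjusted p of 2.3e-16, an adjusted p of 0.579 with an estimated correlation, and a fry adjusted p of 0.048. With the brightest probeset of each gene, ICAM1 had 0.49 (adjusted p = 0.363) and TNFAIP3 3.26 (adjusted p = 0.0664).

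Among apoptosis effectors, 2 of 22 rose: TNFSF10, the death ligand TRAIL, by 2.45 (SE 0.119) and PMAIP1, the BH3-only protein NOXA, by 1.87 (SE 0.121). Camera did not call this list (adjusted p = 0.114), and fry did (adjusted p = 0.0279). The list of leukocyte markers had 4 of 17 members higher. These were S100A8, which rose by 5.93 (SE 0.121) and pairs with S100A9 as calprotectin, and S100A9, by 2.80 (SE 0.221). The others were the MHC class II gene HLA-DRA, by 2.94 (SE 0.205), and CD74, by 2.52 (SE 0.156). CD3D, CD14, PTPRC and LYZ had -0.11, 0.46, 0.28 and 0.02 and did not pass. The camera adjusted p of the leukocyte list was 0.000727, and the adjusted p was 0.579 with an estimated correlation and 0.0547 with fry. Its median was 0.23, and 0.05 without control replicate 2. Among progesterone and glucocorticoid receptor targets, S100P, STAT5A and KLF4 rose by 2.38, 2.28 and 1.55, and SGK1 fell by 1.22 on the log2 scale. SGK1 had an adjusted p of 0.0943 without mimic replicate 2, of 0.0693 with probesets above the table's median and of 0.362 with its brightest probeset. Camera's direction for that list was up, while its median was -0.18 (adjusted p = 0.455).

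In all, 363 of 15719 genes passed the threshold, of which 239 rose and 124 fell, and 3212 had an unadjusted p under 0.05. Of the genes that rose, 203 did so by at least 1 on the log2 scale, 105 by at least 2 and 25 by at least 4. Of those that fell, 59 did so by at least 1 and 1, ACO1, by at least 2. With the replicate block 498 genes passed, 338 of them also without it, and 195 fell. The count was 172 without mimic replicate 1, 186 without mimic replicate 2, 1691 without control replicate 1 and 690 without control replicate 2. Without a filter it was 1433, with an intensity trend 1594 and with the brightest probeset 122.

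ACO1, the cytosolic aconitase that also acts as an iron regulatory protein, fell by 2.09 on the log2 scale (SE 0.130), from 8.47 ± 0.125 (SD, n = 2) to 6.38 ± 0.050 (SD, n = 2), a 4.26-fold lower level with a limma adjusted p of 0.00207. The next largest decreases were those of ADD3, a protein of the membrane skeleton, by -1.61 (SE 0.192), the protease inhibitor SPINK5 by -1.58 (SE 0.122) and ACBD7 by -1.52 (SE 0.190). KHK, the fructose kinase, GLT8D2, the histone gene H2AC12, the mitochondrial creatine kinase CKMT2, the Notch target HEY2, CDKN2AIPNL, the small heat shock protein CRYAB and TP53INP1, a p53-induced gene, changed by -1.47 to -1.34. H2AC12 was read by 1 probeset and KHK by 2, and the mimic level of KHK was 3.95, at the background level. The mimic levels of SPINK5, ACBD7, GLT8D2 and CRYAB, at 5.47, 5.42, 5.14 and 5.66, also lay within the background range of up to 5.68. Without mimic replicate 1, ADD3, ACBD7, H2AC12 and CDKN2AIPNL missed the threshold, at changes of -1.41, -1.33, -1.43 and -1.26. Without mimic replicate 2, H2AC12, HEY2 and TP53INP1 missed it, at -1.42, -1.15 and -1.27. HEY2 also missed the threshold with equal array medians, probesets above the table's median and the median of probesets (adjusted p = 0.0627, 0.0609 and 0.085), and ACBD7 with the last of these (adjusted p = 0.164). With the brightest probeset 10 of these 12 genes did not pass, at changes from -2.35 for HEY2, -1.70 for KHK and -1.42 for H2AC12 to -0.36 for CDKN2AIPNL, and ACO1 and TP53INP1 did.

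DNA replication genes were lower as a list. Of 39 measured members, 3 fell, 36 did not pass and none rose, and 22 were lower when adjusted over the list alone. The helicase subunit MCM6 fell by 0.93 on the log2 scale (SE 0.117), and GINS4 and GINS2, which hold the helicase to the fork, fell by 1.04 (SE 0.131) and 1.08 (SE 0.146). TK1, the thymidine kinase of S phase, had -0.68 (adjusted p = 0.0715) and PCNA 0.04 (adjusted p = 0.871). The list median was -0.47, with a camera adjusted p of 2.0e-11 and an adjusted p of 0.579 with an estimated correlation. Fry did not call the list (adjusted p = 0.0834), and with the brightest probeset its median was -0.31. MCM6, GINS4 and GINS2 missed the threshold with either mimic array left out, at similar changes. These were -0.91, -1.08 and -1.02 without mimic replicate 1 and -0.96, -0.99 and -1.15 without mimic replicate 2. In the same order the adjusted p was 0.0629, 0.0645 and 0.0853 with the median of probesets and 0.3, 0.0989 and 0.186 with the brightest probeset.

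Another 4 lists were lower by camera, and in each limma called 0 members. Counts at an unadjusted p under 0.05 stand against 3212 of all 15719 genes, in either direction. Of 43 genes of G2/M and mitosis, 42 had a value below 0, 14 were lower at an unadjusted p under 0.05, and the median was -0.32. KIF2C, a microtubule depolymerase, had -0.70 (adjusted p = 0.063), ANLN, a scaffold of the cleavage furrow, -0.59, HMMR -0.68 and the condensin subunit NCAPG -0.45. Of 30 cytosolic ribosomal proteins, 13 were lower at an unadjusted p under 0.05 and the median was -0.30, with RPL8 at -0.70, RPL15 at -0.61, RPL22 at -0.51 and RPS2 at -0.75. Of 19 genes of cholesterol synthesis, 11 were lower and 1, STARD4 with 0.37, was higher at an unadjusted p under 0.05 and also when adjusted over the list alone. The median was -0.40, with the sterol reductase TM7SF2 at -0.78 (adjusted p = 0.0579, and 0.0499 with the replicate block), PMVK at -0.56, EBP at -0.51 and mevalonate kinase MVK at -0.68. MVK had 0.01 with its brightest probeset. Of 28 genes of oxidative phosphorylation, 11 were lower and 1, SDHD with 0.42, was higher at an unadjusted p under 0.05, and the median was -0.25, with NDUFA4 at -0.65, SDHC at -0.78, NDUFS1 at -0.52 and UQCRC1 at -0.46. Camera's adjusted p was 5.5e-08, 1.9e-06, 0.000727 and 0.000819 in the order given. Adjusted over the list alone, 0 genes of G2/M and mitosis, 2 ribosomal proteins and 0 genes of oxidative phosphorylation were lower. The adjusted p was 0.590 for G2/M and mitosis and 0.579 for the other 3 lists with an estimated correlation, and fry called none of the 4. With the brightest probeset of each gene the cholesterol list had a median of -0.18 and a camera adjusted p of 0.106, and the medians of G2/M and mitosis and of oxidative phosphorylation were -0.18 and -0.15. SDHD and STARD4 were chosen after their values were seen.

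**Figure D2:**
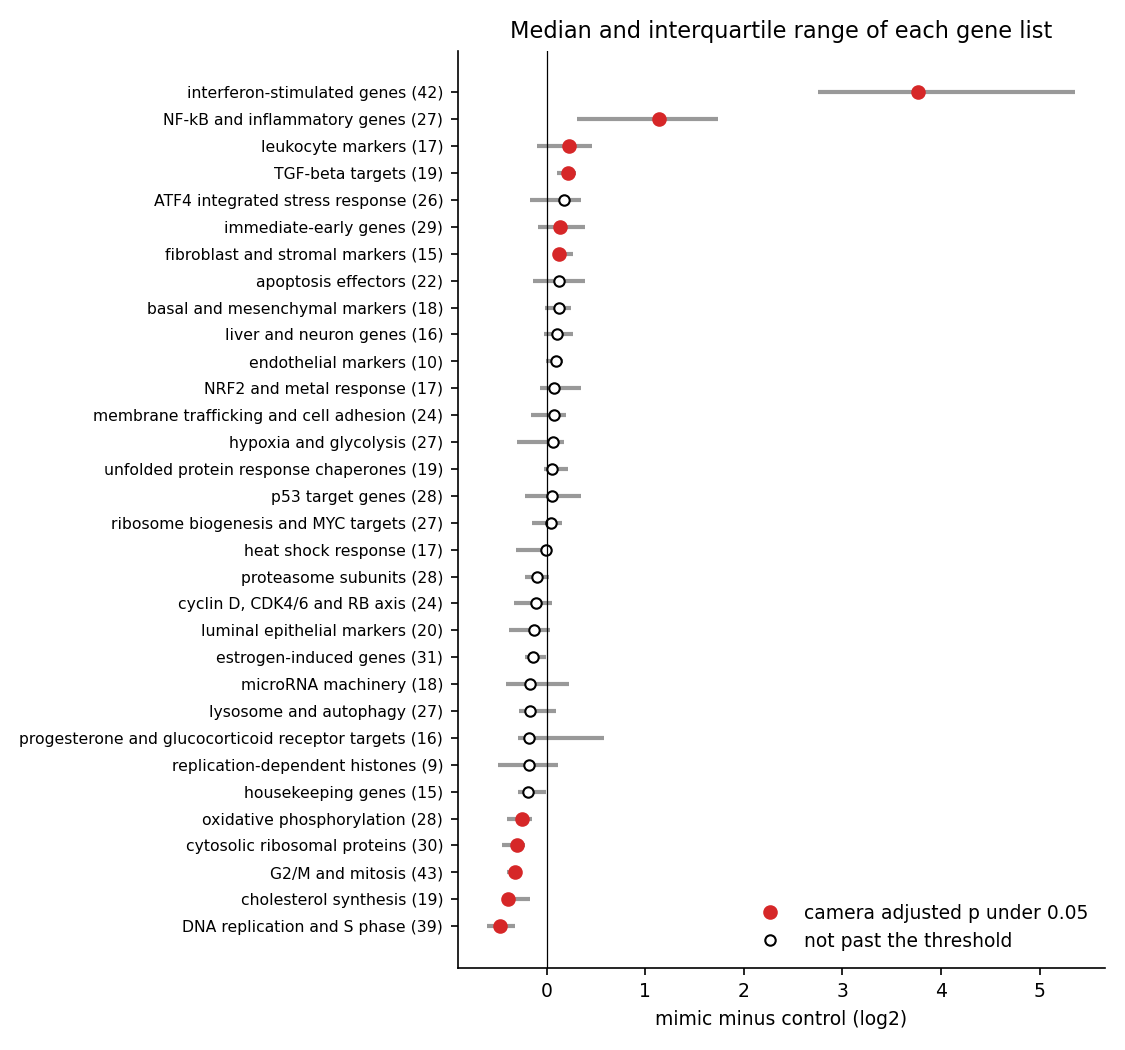
Median (point) and interquartile range (bar) of the log2 change, mimic minus control, over the measured members of each of 32 lists, whose number stands in parentheses. Filled points are the 11 lists with a camera adjusted p under 0.05, from interferon-stimulated genes at 3.77 to DNA replication at -0.47. None of them passed with an estimated correlation (adjusted p from 0.579 to 0.590), a test that rests on 2 residual degrees of freedom.

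Camera also called immediate-early genes (median 0.14, adjusted p = 0.0343), TGF-beta targets (median 0.22, adjusted p = 0.00983) and fibroblast and stromal markers (median 0.13, adjusted p = 0.0469) as higher, and limma called 0 of their 29, 19 and 15 members. The adjusted p was 0.579, 0.579 and 0.590 with an estimated correlation, and fry called none of these lists. At an unadjusted p under 0.05, which 3212 of all 15719 genes had, 9, 4 and 2 members were higher, and 1, 1 and 0 were lower. Those lower were PHLDA1, with -0.38 and chosen after its value was seen, and PMEPA1. KLF6, SPRY4, JUNB and SPRY2 had 0.65, 1.16, 0.73 and 0.58, of which SPRY4 and JUNB passed with the replicate block (adjusted p = 0.0347 and 0.049). SKIL, TGFB2, SMURF1 and PMEPA1 had 0.64, 0.73, 0.42 and -0.48, and FAP, LUM, COL3A1 and POSTN had 0.77, 0.80, 0.31 and 0.37. Without mimic replicate 2 the adjusted p was 0.0589, 0.105 and 0.068. Without control replicate 1 it was 0.0907 for immediate-early genes and 0.129 for TGF-beta targets, and for fibroblast markers it was 0.0954 without mimic replicate 1 and 0.144 without control replicate 2. Without control replicate 1 the median was 0.32 for immediate-early genes and 0.35 for fibroblast markers, and without control replicate 2 it was 0.08 and 0.06. Immediate-early genes also missed the threshold without a filter (adjusted p = 0.0539), with probesets above the table's median (median 0.03, adjusted p = 0.187) and without shared genes (adjusted p = 0.0688), and TGF-beta targets with the brightest probeset (adjusted p = 0.0573). The fibroblast markers missed it with quantile normalization (adjusted p = 0.0906), equal array medians (adjusted p = 0.0542), cyclic loess (adjusted p = 0.0878), no filter (adjusted p = 0.153) and no shared genes (adjusted p = 0.0566). Their mean level was 5.36, within the background range of up to 5.68, and FAP, LUM, COL3A1 and POSTN lay within it in both groups. The liver and neuron genes that serve as background had a median change of 0.10 (camera adjusted p = 0.192).

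CDK4 was lower in the mimic arrays on all 11 of its probesets, and on each of them both mimic arrays lay below both control arrays. Its gene level was 10.91 ± 0.050 (SD, n = 2) in control and 10.33 ± 0.017 (SD, n = 2) in mimic arrays, a difference of -0.58 (SE 0.119) with a 95% confidence interval from -0.88 to -0.28. The limma p was 0.0039 unadjusted and 0.0822 adjusted, so CDK4 missed the threshold. The 8 probesets above 10 in the control arrays had a median change of -0.39, and the 3 dimmer ones of -1.18. The F test for unequal change across probesets called CDK4 (adjusted p = 0.0343), a test that made many false calls in simulated data with unequal probeset variance. Of 459 genes whose mean level lay within 0.5 of that of CDK4, 21 (4.58%) had a larger decrease, as had 666 of all genes tested. CDK4 passed without a filter on dim probesets (adjusted p = 0.0172) and with an intensity trend (adjusted p = 0.00567), and its change was -0.21 on its brightest probeset (adjusted p = 0.569), the ends of the range over the alternatives being 0.00567 and 0.569.

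**Figure D3:**
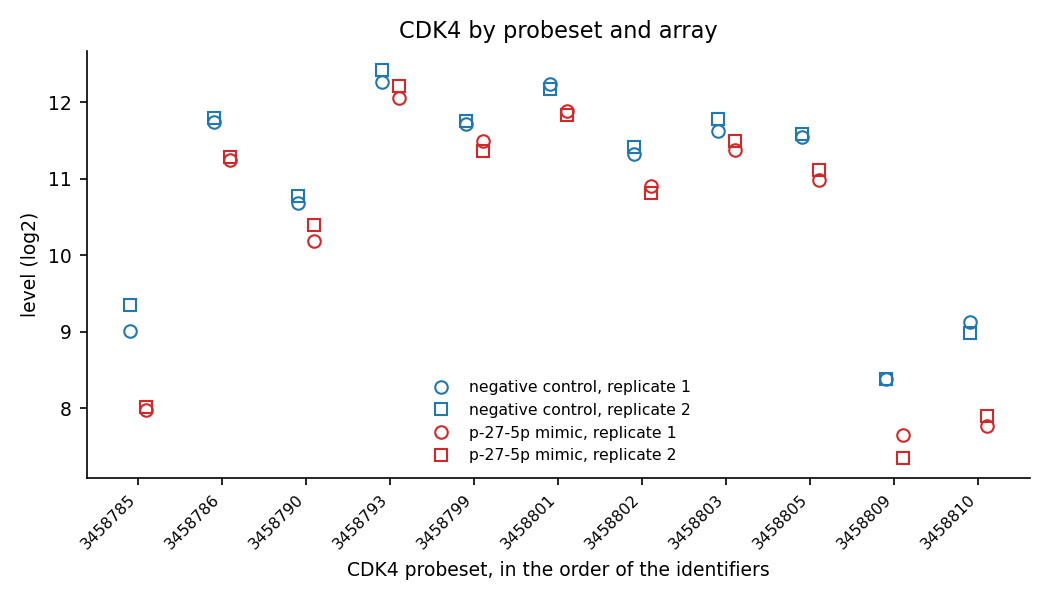
Log2 level (vertical axis) of each of the 11 CDK4 probesets (horizontal axis, in the order of their identifiers) on the 4 arrays, with 1 point per array. Both mimic arrays, in red, lie below both control arrays, in blue, at every probeset, with changes from -1.22 to -0.21.

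Limma called 0 of the 24 genes of the cyclin D, CDK4/6 and RB axis. At an unadjusted p under 0.05, which 3212 of all 15719 genes had, 5 were lower and 2 higher. Adjusted over the list alone, 5 were lower and 1 was higher. CDK2, the partner of cyclin E, had -0.75 (adjusted p = 0.0911, and 0.0483 with the replicate block), E2F1 had -0.62 (adjusted p = 0.106) and E2F3 had 0.57 (adjusted p = 0.0857). CCND1, CDK6 and CDKN1A, which encodes p21, had -0.01, -0.07 and 0.01. The list median was -0.10, with a camera adjusted p of 0.151. With the brightest probeset of each gene it was -0.16, and camera called the list lower (adjusted p = 0.0277), with an adjusted p of 0.374 with an estimated correlation. The median was -0.20 without mimic replicate 1 and -0.17 without control replicate 1, and the camera adjusted p was 0.238 and 0.0837.

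Camera called none of the other 18 lists, with adjusted p between 0.141 and 0.796. They include p53 targets (median 0.06), estrogen-induced genes (-0.14), unfolded protein response chaperones (0.06), hypoxia and glycolysis (0.06), proteasome subunits (-0.10) and endothelial markers (0.09). Single members of them passed. B2M, the light chain of MHC class I, rose by 1.82, a 3.54-fold change, among the housekeeping genes. ADAR, the double-stranded RNA editing enzyme, rose by 1.11 (SE 0.123) in the list of microRNA machinery. CEBPB rose by 0.95 in the ATF4 list. PHGDH, of serine synthesis, had -0.79 (adjusted p = 0.049, and 0.0522 with the replicate block), and HK2, a hexokinase, had 0.83 (adjusted p = 0.046, and 0.051 with the block). MT1A, a metallothionein read by 1 probeset, was 2.01-fold higher (adjusted p = 0.0407, and 0.0534 with the block), and its levels of 4.90 and 3.89 lay within the background range. The linker histone H1-5 fell by 1.22 on the log2 scale, integrin ITGAV by 1.10 and the estrogen-induced gene TFF3 by 0.99. Of these single members B2M alone passed with either mimic array left out, and B2M missed the threshold with its brightest probeset (1.35, adjusted p = 0.0669). For the others the adjusted p was 0.0769 to 0.275 without mimic replicate 1 and 0.0559 to 0.241 without mimic replicate 2. It was 0.0564 to 0.119 with the median of probesets for all but ADAR, and 0.0842 to 0.34 with the brightest probeset for all but H1-5. Limma called 0 of the 20 luminal markers. At an unadjusted p under 0.05, which 3212 of all 15719 genes had, 5 were lower, among them ESR1 with -0.42, the estrogen receptor. ESR1 had 0.026 with its brightest probeset.

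At the level of single probesets, 1543 of 174802 passed, 1389 higher and 154 lower. The F test for unequal change called 433 of 14389 genes, of which 153 also passed at gene level. DOCK1, an activator of RAC, had a gene change of -0.92 (adjusted p = 0.0657, and 0.0376 with the replicate block) that was uneven along its probesets. Its probesets 2 to 25 of 50, in the order of their identifiers, changed by -2.76 to -1.19, with 12 past the threshold, and probesets 26 to 50 by -0.55 to 1.03. The first of these parts was also the brighter one, with control levels of 7.15 to 11.12 against 4.38 to 7.40. NLRC5, the activator of MHC class I genes, had changes from 0.43 to 5.30 over 48 probesets, and HELZ2, a helicase, from 0.75 to 4.66 over 29. In simulated data with unequal probeset variance 253 of 365 calls of this test were false, so the count of 433 is not a count of changed transcripts. It was 1214 with the replicate block. The test of single deviations called 0 genes, but it had recovered 0 of 200 simulated genes, so its 0 calls say little. In that test 13488 of 162444 probesets (8.30%) had an unadjusted p under 0.05.

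**Figure D4:**
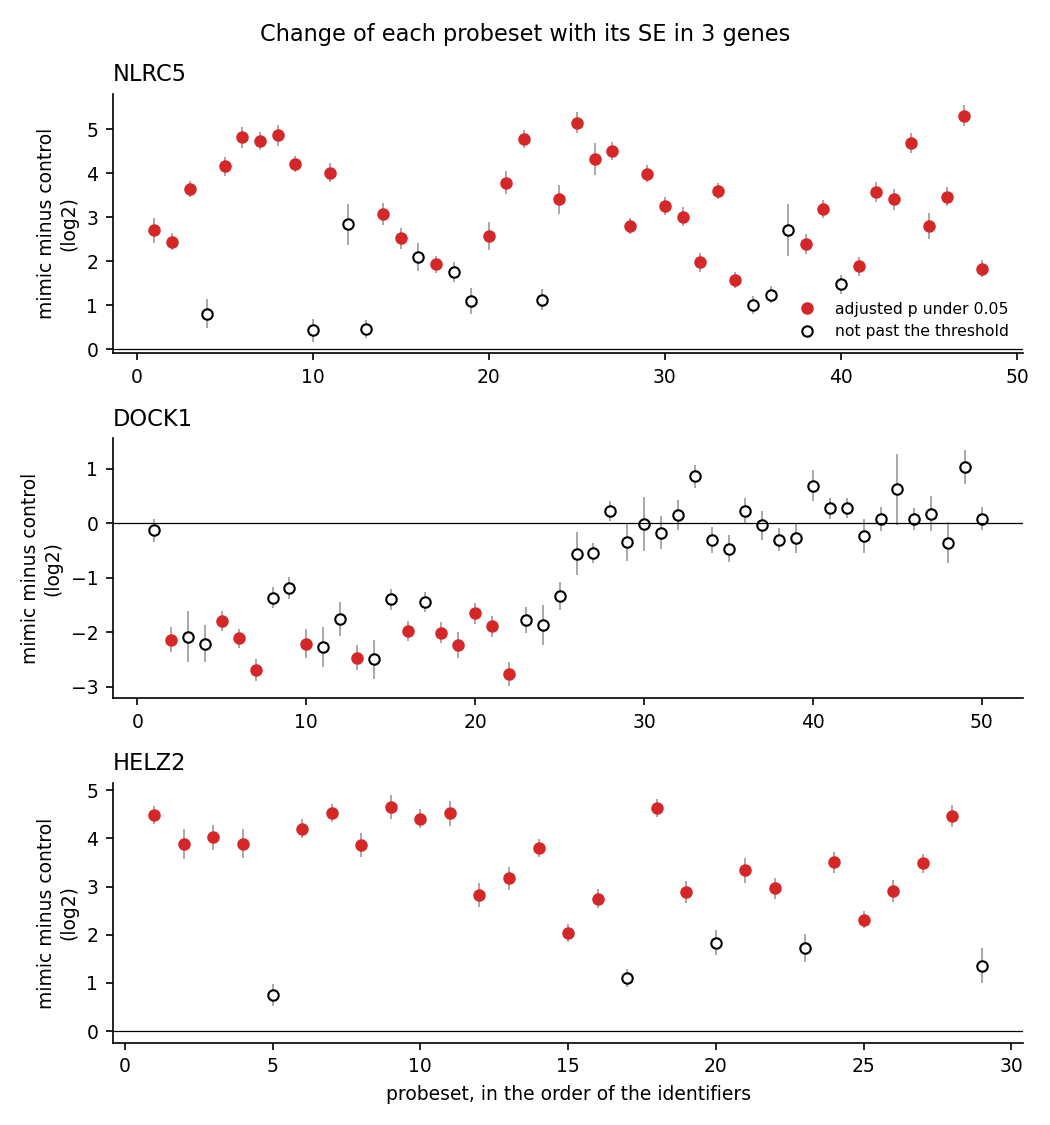
Log2 change, mimic minus control (vertical axis), of each probeset of NLRC5, DOCK1 and HELZ2 in the order of the identifiers (horizontal axis), with limma's SE as bars and filled points for probesets with an adjusted p under 0.05. DOCK1 probesets 2 to 25 lie between -2.76 and -1.19 and the later ones between -0.55 and 1.03.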

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

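The tests of leukocyte RNA, of the list call of oxidative phosphorylation after quantile normalization, of dim probesets in genes changed by under 0.5 and by 0.5 to 1, and of unequal variance in genes changed by under 0.5, were chosen after the result was seen. The comparison with differences between replicates was added once the simulation had been seen to leave unequal variance open. Outside the comparison of named genes, 32 unnamed probesets and 26 probesets with several gene names were higher in the mimic than in the control arrays. They are signals in rows that the gene-level comparison does not use. Of 9268 unnamed probesets tested, 39 passed, 7 of them lower. Of 1760 with several names, 27 passed, 1 of them lower.

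The rise of the interferon-stimulated genes does not rest on 1 array, since the lowest list median over the 4 pairs of a mimic and a control array was 3.77, with 42 of 42 genes higher in each pair. RNA of a mix of leukocytes as the source of this rise is argued against by the 17 leukocyte markers, whose median was 0.2282 with an interquartile range of 0.564. The 7 of them above the background range in the control arrays had a median of 0.23 with an interquartile range of 0.488. The markers are of several kinds of leukocyte, so these medians could miss RNA of 1 kind. Of the 17, 4 were called higher (S100A8, S100A9, HLA-DRA and CD74), but PTPRC and LYZ, abundant in leukocytes, were at 4.81 and 5.08 in the mimic arrays, below the highest background level of 5.68. All 4 samples were of the T-47D line, so the rise is read as a response of these cells themselves. Whether it came from the sequence, the double-stranded form, the dose or the preparation of the mimic stays open. These were not tested, since the design holds 1 mimic and 1 control.

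The mimic arrays had on average a narrower range of values (interquartile range 4.18 and 4.32, against 4.25 and 4.52), which can lower bright genes. After quantile normalization, the median was -0.4458 for DNA replication, -0.2704 for G2/M and mitosis, -0.2993 for ribosomal proteins and -0.3526 for cholesterol synthesis. Each lay below the 2.5th percentile of 10000 random lists matched on mean level, which were at -0.18, -0.19, -0.21 and -0.23, so the range does not account for them as a whole. Oxidative phosphorylation went from -0.25 to -0.21 and was still called by camera (adjusted p = 0.002593), which argues against the range as its whole cause. With an estimated correlation, where camera rests on 2 residual degrees of freedom, the adjusted p was 0.443. The list lay at percentile 2.71 of its random lists, whose median was -0.10, so a decrease shared by genes of its level stays open. Random lists of single genes ignore correlation between members, and slower growth of the cells was not tested.

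The genes with unequal change fall into parts. Among 135 with a gene change of at least 1, 54.81% still passed with probesets above the table's median, which leaves dim probesets open for the rest. Among the 113 with a change of 0.5 to 1, 46.02% still passed, CDK4 and DOCK1 among them, and among the 185 with a change under 0.5, 42.16%. CDK4 kept all 11 of its probesets, so this limit could not test dim probesets there. Dim probesets stay open for the genes that no longer passed. In DOCK1 the brighter part was the one that fell. At control levels of 7.12 to 7.40, though, its probesets 10 and 24 changed by -2.21 and -1.86, and probesets 38, 40 and 43 by -0.30, 0.69 and -0.23. Level alone therefore does not account for the difference at these probesets. For the 185, single probesets that read wrongly are argued against as the cause of all by neighbouring probesets that deviated together (lag-1 autocorrelation 0.1503, against -0.105 to -0.032 in shuffled orders), but they stay open for 50 of the 172 genes with 6 or more probesets, where 1 probeset held over 50% of the squared deviation. Unequal variance can produce calls in such numbers, as 253 false calls in simulation show, but as the cause of all of them it is argued against by the differences between replicates in the same genes, whose autocorrelation reached only -0.04174. How many of the 185 are false stays open, and different transcript isoforms remain an untested hypothesis.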

How the results depend on the processing

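Cyclic loess normalization, the test of single probesets' deviations, and an estimated correlation with the brightest probeset or after quantile normalization were added after the data were seen. Over 1790 values of 129 named genes besides CDK4 under alternatives, 1563 kept direction and side of the threshold, 98 lost and 99 gained the call, and 30 reversed, in 13 genes that missed the threshold as reported. With the brightest probeset the reversed values were MVK 0.01478, CCND1 0.04785, CDK6 0.4208, CDKN1A -0.4017, ESR1 0.02585, RABGAP1L -0.2006, IRF5 -0.1615 and TFRC 0.03795. Without a filter they were CD3D 0.1354 and PCNA -0.02605, above the table's median IRF5 -0.1265, and with the median of probesets CCND1 0.01004. Quantile normalization gave LYZ -0.032, CCND1 0.03789 and SOCS3 -0.03575, cyclic loess CCND1 0.0654 and SOCS3 -0.009617, and equal medians CCND1 0.01296. With 1 array left out LYZ ran from -0.2329 to 0.2826, CCND1 from -0.07215 to 0.06069, CDK6 from -0.2236 to 0.08359, CDKN1A from -0.06949 to 0.0903, SOCS3 from -0.0299 to 0.04705 and CGAS from -0.1161 to 0.3976. The 12 largest increases and ACO1 kept theirs in all 14 alternatives run on them. CDK4 stayed below 0 in all 14, and passed the threshold at -0.58 without a filter and at -0.58 with an intensity trend.

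Genes called, of 363 (239 higher, 124 lower): 1433 (540, 893) without a filter, 122 (115, 7) with the brightest probeset, 1594 (527, 1067) with an intensity trend and 979 (452, 527) at an adjusted p under 0.1. Genes lower were 195 with the replicate block, 222 after quantile normalization, 55 with the median of probesets and 59 at a change of at least 1 on the log2 scale. The blocked fit ended the calls of 3 named genes (PHGDH, HK2 and MT1A), added 6 (XAF1, TM7SF2, SPRY4, JUNB, CDK2 and DOCK1) and changed no other call of a named gene. It ended no call of a list (11) and CDK4 still missed the threshold (adjusted p = 0.059). The share higher among calls was 65.8% as deposited, 58.5% after quantile normalization, 71.5% with equal medians and 65.6% with cyclic loess. Quantile normalization and cyclic loess shared 362 genes with the 363.

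Leaving out 1 array gave 172 to 1691 genes (160 to 983 higher, 12 to 708 lower), the extremes being without mimic replicate 1 and without control replicate 1, with 186 without mimic replicate 2 and 690 without control replicate 2. It gave 616 to 940 probesets, of 1543, and 85 to 244 genes with unequal change, of 433. Probesets called were 4828 with an intensity trend. Lists called, of 11, were 0 with an estimated correlation (2 at an unadjusted p under 0.05), also 0 with it and the brightest probeset or quantile normalization, and 3 with fry. Genes with unequal change were 1214 with the replicate block, 256 above the table's median, 780 with Simes and 0 with single deviations. The last of these tests had recovered 0 of 200 simulated genes. The causes were not tested. Signal near background limits genes below about 5.68 on the log2 scale.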

Other observations

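The 7 gene lists used here, and RABGAP1L, were chosen after the data were seen, so their directions are not independent evidence. Genes of MHC class I antigen presentation were higher. Of 15 measured, 13 rose and 2 did not pass, with a median of 1.82. HLA-F rose by 3.71, NLRC5, the activator of these genes, by 2.94, the peptidase ERAP2 by 2.38, and TAP1, a subunit of the peptide transporter, by 1.68. The immunoproteasome subunits PSMB9, PSMB8 and PSMB10 rose by 3.08, 2.22 and 2.09. Camera gave an adjusted p of 7.1e-22, and the adjusted p was 0.0628 with an estimated correlation. Of 12 guanylate-binding proteins and other genes of the interferon-gamma type, 4 rose: GBP4 by 3.80, GBP1 by 3.17, ICAM1 by 2.46 and GBP2 by 1.31. Camera's adjusted p was 1.5e-10, and the adjusted p was 0.0702 with an estimated correlation. SOCS3 had 0.01 (adjusted p = 0.979). With the brightest probeset HLA-F, NLRC5, TAP1, PSMB8, PSMB10 and GBP2 had adjusted p of 0.08 to 0.778, and without mimic replicate 1 GBP2 had 0.129. GBP2 also missed the threshold with equal array medians (0.0627) and with the median of probesets (0.0635).

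Of 17 nucleic acid sensors and adaptors, 5 rose: TLR3, an endosomal sensor of double-stranded RNA, by 3.45, IRF1 by 3.36, the DNA sensor IFI16 by 3.25, MYD88 by 1.15 and TRIM25 by 0.88. IRF5 and CGAS had 0.07 and 0.14 and did not pass. Among 13 genes of interferon receptors and signalling, IRF9 and STAT2 rose by 2.23 and 2.00, while IFNAR1 had -0.35 (adjusted p = 0.346). Among 14 genes of necroptosis and pyroptosis, CASP1 rose by 4.49 and CASP4 by 1.63, and IL18, a cytokine that CASP1 matures, fell by 1.13 on the log2 scale. Of 12 iron handling genes ACO1 alone passed, and the transferrin receptor TFRC had -0.40 (adjusted p = 0.158). Among 9 S100 genes, S100A8, S100A9 and S100P passed, and S100A16 and S100A10 had -0.42 and -0.27 and did not pass. MYD88, TRIM25 and IL18 missed the threshold with either mimic array left out. Over the fits with 1 array left out their changes ran from 1.056 to 1.246, from 0.8136 to 0.9543 and from -1.152 to -1.115. With the brightest probeset their adjusted p was 0.128, 0.158 and 0.316, and that of TLR3 was 0.151. With probesets above the table's median TLR3 had 2.85 (adjusted p = 0.0577), and with the median of probesets the adjusted p was 0.0657 for TRIM25 and 0.0676 for CASP4. Camera's adjusted p of these 5 lists, in the order given, was 1.3e-06, 0.00015, 0.0020, 0.43 and 0.0068 at the preset correlation. With an estimated correlation it was 0.134, 0.219, 0.134, 0.497 and 0.145. Fry's adjusted p was 0.00996, 0.0188, 0.00077, 0.026 and 0.00077.

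RABGAP1L had a gene change of 0.39 (adjusted p = 0.168) over 35 probesets, whose changes ran from -0.97 to 2.88. Its probesets 22 to 35, in the order of the identifiers, were all above 0, from 0.49 to 2.88, and 1 of them passed alone.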
